A study of Mus musculus with 2 samples.

How the data were processed

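RNA was measured by Illumina sequencing in 2 libraries of mouse acute myeloid leukaemia (AML) cells. Per the labels, the cells were leukaemia-initiating cells sorted from bone marrow for surface Mac1 (encoded by Itgam) and c-Kit (encoded by Kit), from C57BL/6 mice aged 8 weeks. Per the labels, RNA was extracted with TRIzol and an RNeasy column kit, and libraries followed standard Illumina protocols. Whether poly(A) RNA was selected is not given in the sources used here. One library is labelled wild type and the other P2x7-KO in the genotype field, while their titles end in Scr and KD. Each group therefore holds 1 library, and whether a library came from 1 mouse or a pool is not given in the sources used here.

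The deposited table holds raw counts per gene for 46095 genes, with a gene type for each and with 0 duplicate names. HISAT2 2.0.4 and the genome build mm10 are named in the submitters' processing notes. The counting program, the gene annotation, the strand setting, the read length and the treatment of reads with several matches are not given in the sources used here, so values of genes with near-identical copies or with overlapping or antisense partners are uncertain. The table has no rows for unassigned reads, and both of its value columns were used (0 columns left out). The counts summed to 12456212 in the library labelled wild type and 12435916 in the library labelled P2x7-KO. Near-equal totals of this size mean that a gene at 0 counts is limited to 0.247 and 0.236 CPM (counts scaled to 1000000 per library), respectively, taking 3 counts as the limit.

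With 1 library per group no test between genotypes was possible, and no p-value was computed. Counts were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3 over all genes, and CPM values are on that scale. The difference between the libraries is the ratio of the scaled count in the library labelled P2x7-KO to that in the library labelled wild type. Its exact 95% counting interval came from the Clopper-Pearson interval of the share of a gene's counts that lay in the former library. CPM intervals are exact Poisson intervals. Reads are not independent molecules, and all intervals and limits cover counting error only, not variation between mice, sorts or library preparations. A gene was called at least 2-fold apart when its ratio was 2 or more in either direction and its interval excluded a ratio of 1, among 13363 genes with at least 20 counts over both libraries. A gene at 0 in one library is given as a lower bound against 3 counts in that library, beside the nearer bound of its counting interval.

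Before the data were examined, 30 gene lists with 648 entries were fixed by symbol, of which 2 names were not found in the table. Ribosomal protein genes and mitochondrially encoded genes were taken as 2 further lists. The mitochondrial genes carry no prefix in the table, so their 13 symbols came from the RefSeq gene table of GRCm38.p6 and not from the prefix planned. For each list the members with at least 20 counts were used. The median log2 ratio, with 0.5 added to each count, was placed among the medians of 10000 random lists of the same size matched in 20 bins of mean expression. Percentiles below 2.5 or above 97.5 are called outside the random lists. They describe these libraries, since genes are not replicates. The interval of a list median came from 500 Poisson redraws of its counts.

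The genes named were fixed by rule before the data were examined. They are P2rx7, the sort genes Kit and Itgam, the preset genes Pbx3, Meis1, Hoxa9 and Bcat1, and the 12 genes higher and 12 lower with the largest nearer bound of the counting interval among named mRNA genes with at least 100 counts. Each list adds up to 4 members in the direction of its median and up to 2 in the other, by the same bound. Genes outside the rule are named as such where they appear, or belong to a list described in the same paragraph and stand there as further members chosen after their values were seen. Some genes that the rule takes are not reported here.

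The interval and the list percentile were tested on simulated data: Poisson counts at the pooled means and the real totals with 200 changed genes. Of the genes changed by 4-fold upward, 100% of 50 were called. At 2.5-fold upward 94% of 50 were called, at 2.5-fold downward 87.5% of 48, at 4-fold downward 97.9% of 47, and 0.47% of 13187 unchanged genes were. Of 1000 simulated unchanged lists of 25 genes, 5.4% lay outside the random lists (here 1000 for each), and of 50 lists raised by 0.3 on the log2 scale 100% did. Apart from the changed genes both simulated libraries had the same means, so their ratios spread less than the real ones. The list rate thus does not carry over: in the real data the median of 17 purinergic genes, 0.39, lay at percentile 91.1. The gene rates cover counting error only. Alternatives were other scalings (total count, the median-of-ratios of DESeq2 1.42.0, upper quartile), thinning to equal totals, other count filters, other fold thresholds, removal of mitochondrial, ribosomal protein and globin genes, another added count and 10 expression bins. Alternatives added after the data were seen subtracted the median log2 ratio of mRNA genes of like transcript length (20 bins) or of like length and GC content (50 bins), or kept the genes with an annotated length without adjustment. Length and GC content are those of the longest GENCODE M21 transcript with the gene's symbol, found for 96.5% of 11316 mRNA genes counted. That transcript need not be the one expressed here, so the adjusted value of a single gene can be off. Coordinates are from GENCODE M21 on GRCm38, the assembly behind mm10. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.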

Results

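By its labels, the series compared wild type with knockout of P2x7, an ATP-gated cation channel encoded by P2rx7, in leukaemia-initiating cells of mouse acute myeloid leukaemia (AML). It holds 2 libraries of Mac1-positive, c-Kit-positive bone marrow cells, 1 labelled wild type and 1 labelled P2x7-KO. The former held 12456212 counts over 18440 detected genes and the latter 12435916 counts over 18983 detected genes. Differences between them have no replicate check, and the intervals given cover counting error only.

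P2rx7 itself was higher, not lower, in the library labelled P2x7-KO. This gene lies on chromosome 5 from 122643911 to 122691432 on the plus strand (mm10, GENCODE M21). It had 229 counts in the library labelled wild type, 18.8 CPM (95% interval 16.5 to 21.4), and 543 counts in the library labelled P2x7-KO, 42.6 CPM (39.1 to 46.4). The ratio was 2.27-fold (1.94 to 2.66), and its log2 value of 1.18 became 0.92 (0.695 to 1.15) after adjustment for transcript length and GC content, which is under 2-fold. The targeted gene thus went against the label, and the libraries are named by their labels throughout. Counts per gene do not show which exons the reads came from, so transcript left by a disrupted allele would be counted too.

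Both sort genes were higher in the library labelled P2x7-KO before adjustment for length and GC content, which checks the sort and is no finding. Kit, on chromosome 5 from 75574916 to 75656722, had 46.0 CPM in the library labelled wild type and 67.6 CPM in the other, a 1.47-fold ratio (1.32 to 1.64). Its log2 ratio of 0.56 became 0.12 (-0.04 to 0.27) after it, an interval that includes equality. Itgam, which encodes the alpha chain of Mac1 on chromosome 7 from 128062640 to 128118491, had 186.9 and 542.6 CPM, a 2.90-fold ratio (2.77 to 3.04). The Itgam log2 ratio of 1.54 became 1.28 (1.21 to 1.35) after adjustment for length and GC content, still past 2-fold. Pbx3, which encodes a homeodomain partner of HOXA9 and MEIS1, was 1.48-fold higher (1.37 to 1.61) at 122.2 against 82.4 CPM. Meis1 was 1.35-fold higher (1.22 to 1.49) at 79.3 against 58.8 CPM, but its log2 ratio of 0.43 turned to -0.27 after adjustment for length and GC content. The Hoxa9 ratio was 1.03 (0.98 to 1.09), at 222.6 against 215.5 CPM. Bcat1, a branched-chain aminotransferase gene, had 1 count in the library labelled wild type and 0 in the other, both within the detection limit.

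**Figure D1:**
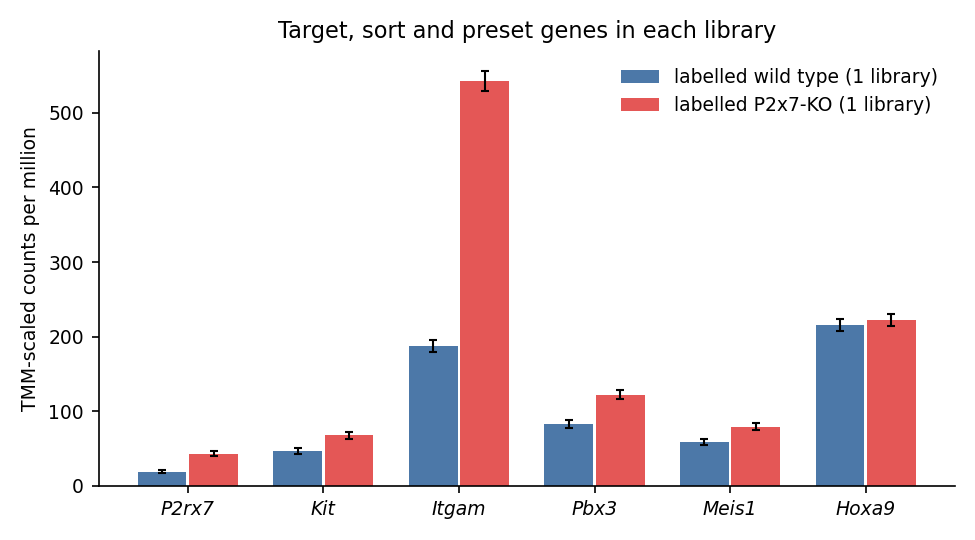
TMM-scaled counts in CPM (vertical axis) of the targeted gene, the sort genes and preset leukaemia genes in each library; bars are 1 library each and error bars are exact 95% Poisson intervals. P2rx7 stood at 18.8 CPM in the library labelled wild type and 42.6 CPM in the library labelled P2x7-KO, and Itgam at 186.9 and 542.6 CPM.

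Of 13363 genes counted, 1447 were at least 2-fold higher and 1196 at least 2-fold lower in the library labelled P2x7-KO, 19.8% of those counted. The genes furthest apart were ranked by the nearer bound of the interval among named mRNA genes with at least 100 counts. Of those that were higher, Pydc4 came first, at 2.88 CPM in the library labelled wild type and 60.3 CPM in the other (20.96-fold, 14.9 to 30.3). Its value is uncertain because it belongs to a family of similar genes whose reads the counting could split. Next came Adam19, a membrane metalloprotease gene, at 18.1-fold (12.6 to 26.9), Stard9 at 12.6-fold (8.89 to 18.4), and the transcription factor gene Dach1, with 8.55 against 92.6 CPM, at 10.8-fold (8.86 to 13.4). The leukaemia inhibitory factor receptor gene Lifr was 11.05-fold higher (8.60 to 14.4), Fnbp1l 9.58-fold (8.31 to 11.1), March1 10.9-fold (8.23 to 14.7) and Ahnak 8.87-fold (7.89 to 9.998). Rnf150, Zfyve9, Tarm1 and F13a1 completed the 12, at 15.02-fold, 16.5-fold, 11.7-fold and 6.65-fold. After adjustment for length and GC content the log2 ratios of Dach1, Lifr, Fnbp1l, Ahnak and Rnf150 were lower, at 2.76, 2.77, 2.43, 2.497 and 3.26, from 3.44, 3.47, 3.26, 3.15 and 3.91.

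Among the 12 genes furthest apart in the other direction by the same ranking, Mycn, a MYC family transcription factor gene, had 191 counts in the library labelled wild type and 0 in the other. It was thus at least 66.6-fold lower in the library labelled P2x7-KO, against 3 counts in that library, and the counting interval, which also covers the error of the 191 counts, reached down to 53.7-fold. The interleukin-25 receptor gene Il17rb stood at 45.95 against 1.57 CPM (29.3-fold lower, 18.8 to 48.3). The mast cell carboxypeptidase gene Cpa3 stood at 333.6 against 21.99 CPM (15.2-fold lower, 13.4 to 17.2), and the neuropeptide Y gene Npy was 16.9-fold lower (12.1 to 24.4). Cfap57 had 209 against 4 counts (54.7-fold lower, 21.05 to 202.6) and the chloride channel gene Cftr 141 against 4 (36.9-fold lower, 14.1 to 137.3). Nrgn had 105 against 2 counts, a ratio of 55.0 (14.8 to 459.8), and Mzb1 99 against 3, a ratio of 34.5 (11.5 to 170.4). Adam11, Hdc, Galnt14 and Ripk4 were 13.8-fold, 11.6-fold, 9.82-fold and 10.7-fold lower. After adjustment for length and GC content the log2 ratios of Npy, Cftr and Mzb1 were -3.49, -5.86 and -4.52, from -4.08, -5.21 and -5.11.

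**Figure D2:**
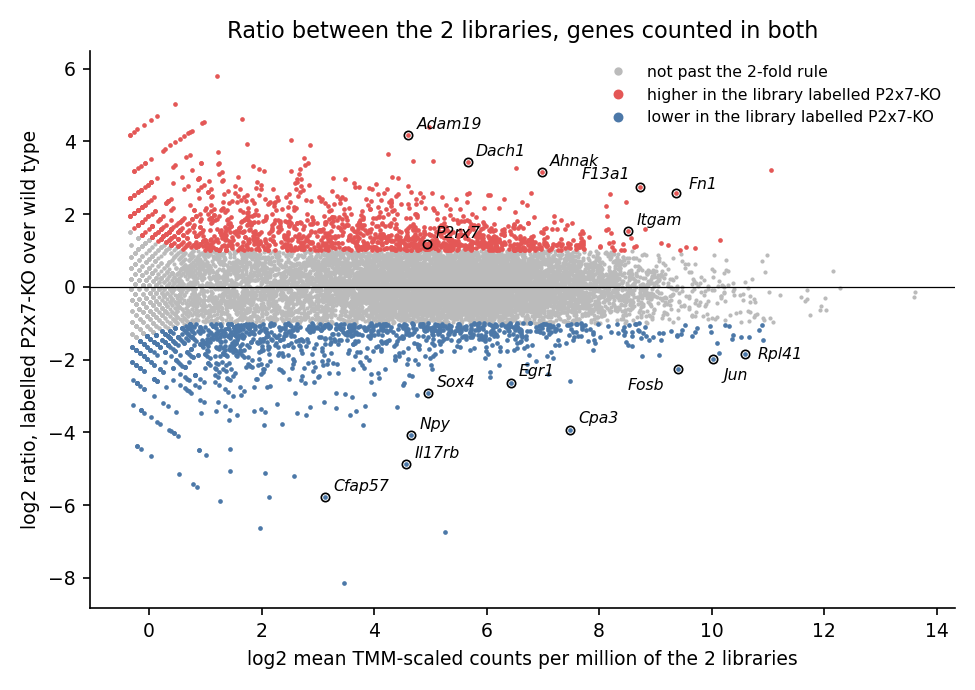
Each dot is a gene with at least 20 counts over both libraries and at least 1 in each; the horizontal axis is the log2 mean of the TMM-scaled counts in CPM and the vertical axis the log2 ratio of the library labelled P2x7-KO to the library labelled wild type. Red and blue mark genes past the 2-fold rule (1447 higher and 1196 lower, with genes at 0 in either library included in those counts), and circles mark some of the genes named in the text.

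Monocyte and macrophage genes stood higher as a group in the library labelled P2x7-KO. Of 27 members counted, 13 were at least 2-fold higher, 1 was lower and 13 were neither, with a median log2 ratio of 0.57 (0.48 to 0.88) at percentile 99.95 of random lists. F13a1, a coagulation factor XIII subunit gene, stood at 110.1 against 732.4 CPM (6.65-fold, 6.28 to 7.05). The fibronectin gene Fn1 stood at 189.7 against 1128 CPM (5.95-fold, 5.69 to 6.22), the monocyte chemokine receptor gene Ccr2 at 5.01 against 32.6 CPM (6.499-fold, 4.96 to 8.65) and Vcam1 at 25.2 against 134.1 CPM (5.33-fold, 4.72 to 6.04). Further members past the rule were Mpeg1 (4.69-fold), Ctss (3.002-fold), the colony-stimulating factor receptor gene Csf1r (2.75-fold) and the lysozyme gene Lyz2 (2.09-fold). Ly6c2 stood at 994.6 and 959.9 CPM, a log2 ratio of -0.05 that total count scaling would turn. Itgam, a sort gene, was higher in the same library.

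Genes of mature neutrophils and their secondary granules had members on both sides. Of 24 counted, 5 were at least 2-fold higher, 3 lower and 16 neither, with a median log2 ratio of 0.46 (0.25 to 0.47) at percentile 99.79. After adjustment for length and GC content 8 were higher and 1 lower, with a median of 0.50. The collagenase gene Mmp8 was 3.89-fold higher (3.37 to 4.503), Fpr2 3.55-fold (2.67 to 4.80) and Olfm4 2.98-fold (2.86 to 3.11). The granulocyte colony-stimulating factor receptor gene Csf3r was at 1.98-fold (1.84 to 2.13), just under the rule, but past it with total count and DESeq2 scaling (log2 ratios 1.05 and 1.02) and after that adjustment (1.08). S100a8 was 2.53-fold lower (2.45 to 2.62) and Stfa2 2.59-fold lower (2.30 to 2.93), and both came under 2-fold after that adjustment. Of 11 primary granule genes, only Calr, which encodes a chaperone of wide expression, passed the rule, at 2.06-fold lower (2.02 to 2.10), and came under 2-fold with total count scaling (log2 ratio -0.97). Mpo stood at 970.7 and 984.4 CPM and Elane at 1617 and 1571 CPM in the libraries labelled wild type and P2x7-KO, and Ctsg was 1.74-fold lower (1.69 to 1.79). The median log2 ratio of this list was 0.02, at percentile 63.2, and turned to -0.01 under upper quartile scaling. Its mean was -0.12, and after adjustment for length and GC content the median was 0.38 at percentile 99.5.

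Several markers of other cell types were higher in the library labelled P2x7-KO, while others, such as Ighm, Il7r and Nkg7, were lower. The globin genes Hbb-bs and Hba-a1 had 1 and 2 counts in the library labelled wild type and 58 and 41 in the other, ratios of 55.4 (9.56 to 2226) and 19.6 (5.09 to 167.1). Tfrc, at 1.11-fold higher, turned to a log2 ratio of -0.41 after adjustment for length and GC content. The 4 erythroid genes counted had a median log2 ratio of 2.07, at percentile 99.96, which is the midpoint between Hba-a1 and Tfrc. Of 6 B lymphoid genes, Jchain (5 against 55 counts, 10.5-fold, 4.24 to 33.6) and Igkc (20 against 122, 5.83-fold, 3.61 to 9.88) were higher. Cd22 was higher too (20 against 98, 4.68-fold, 2.87 to 8.00). Ighm, with 892 against 395 counts, was 2.36-fold lower (2.10 to 2.67). Mzb1, a B cell gene outside this list, was 34.5-fold lower, at 99 against 3 counts. As 3 of the 6 lay above equality and 3 below, their median of 1.07, at percentile 99.05, is a midpoint between the sides. The list median was 0.78 at percentile 88.6 without the count filter. Of 9 dendritic cell and MHC class II genes, 4 were higher and 0 lower, with a median of 0.65 at percentile 95.4: Siglech (3 against 25 counts, ratio 7.96, 2.43 to 41.2), H2-DMa (4.90-fold, 2.80 to 9.18), Cd74 (2.84-fold, 2.25 to 3.61) and Irf4 (2.48-fold, 1.34 to 4.85). Tcf4 was 1.497-fold lower. After adjustment for length and GC content 4 were higher and 1 lower, with a median of 0.97 at percentile 99.6, and the lower one was Tcf4 at a log2 ratio of -1.42 (-1.48 to -1.35). Of 5 T and NK lymphoid genes, Ccl5 was higher (2.59-fold, 1.04 to 7.30) while Il7r (4.08-fold, 2.71 to 6.32) and Nkg7 (3.06-fold, 2.44 to 3.86) were lower. Their median of 0.67, at percentile 87.3, and mean of -0.15 differed in sign, and after that adjustment 2 were higher and 2 lower.

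Some mast cell, basophil and early progenitor genes, and the megakaryocyte gene Itga2b, were lower in the library labelled P2x7-KO. The medians of the lists that hold them lay within the random lists. Cpa3 and the histidine decarboxylase gene Hdc (11.6-fold, 7.63 to 18.4) were lower among 6 mast cell and basophil genes, and Il6ra was 4.77-fold higher (4.31 to 5.30). The basophil protease gene Mcpt8 was at 1.43-fold lower (1.19 to 1.73), not past the rule. Its log2 ratio of -0.52 became -0.06 (-0.33 to 0.21) after adjustment for length and GC content. The list median was -0.41, at percentile 7.90. Of 4 megakaryocyte genes, Itga2b was 4.34-fold lower (3.53 to 5.38) and Vwf 3.38-fold higher (2.17 to 5.44), with a median of 0.40 at percentile 77.35 that turned to -0.03 after adjustment for length alone. Of 12 stem and progenitor genes, Gfi1b (8.95-fold, 5.74 to 14.6), the immediate early gene Egr1 (6.19-fold, 5.48 to 7.01) and Mllt3 (6.15-fold, 2.88 to 15.1) were lower, and Cd93 (2.57-fold, 2.43 to 2.73) and Txnip (2.14-fold, 2.04 to 2.25) higher. Gata2 was at 1.99-fold lower (1.84 to 2.16), and past 2-fold with upper quartile scaling (log2 ratio -1.03), without abundant gene classes (-1.003) and after adjustment for length alone (-1.08). It stayed under 2-fold with total count (-0.93) and DESeq2 scaling (-0.96). After adjustment for length and GC content it was also under 2-fold, at -0.86 (-0.98 to -0.75). The median of that list was -0.47 (-0.70 to -0.15), at percentile 2.5 and so at the limit, and at percentile 0.12 after adjustment for length and GC content, with 4 then lower and 1 higher.

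In the HOXA-MEIS1-PBX3 leukaemia list, 0 of 23 members counted were at least 2-fold higher and 4 were lower. Sox4 was 7.55-fold lower (6.07 to 9.49), at 55.2 against 7.30 CPM, and the transcriptional coactivator gene Eya1 was 4.06-fold lower (3.35 to 4.95). Hoxa11 had 22 counts in the library labelled wild type and 0 in the other, at least 7.68-fold lower against 3 counts, with a counting interval that reached down to 5.73-fold. Mef2c and Cdk6 were 1.78-fold (1.69 to 1.86) and 1.66-fold higher (1.62 to 1.70), with log2 ratios of 0.83 and 0.73 that became 0.18 and 0.03 after adjustment for length and GC content. The list median was -0.08 (-0.17 to 0.02), at percentile 31.0, and -0.08 with Hoxa11 at its bound.

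Immediate early and heat shock genes stood lower as a group in the library labelled P2x7-KO. Of 21 counted, 13 were at least 2-fold lower, 0 higher and 8 neither. The median log2 ratio was -1.12 (-1.21 to -1.09), below all 10000 random lists, and -0.85 after adjustment for length and GC content, again below all of them, with 8 then at least 2-fold lower and 0 higher. The phosphatase gene Dusp2 was 5.23-fold lower (4.77 to 5.74) and the AP-1 subunit gene Fosb, at 1117 against 231.3 CPM, 4.83-fold lower (4.64 to 5.03). Jun stood at 1664 against 418.2 CPM (3.98-fold lower, 3.86 to 4.10), Ier3 was 3.94-fold lower (3.23 to 4.84), and Fos stood at 1005 against 406.5 CPM (2.47-fold lower, 2.39 to 2.55). The heat shock gene Hspa8 was 1.61-fold lower (1.57 to 1.64).

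Genes of the integrated stress and unfolded protein response were also lower in the middle of their list, with 4 of 21 at least 2-fold lower and 1 higher. The serine synthesis gene Phgdh was 5.07-fold lower (4.46 to 5.79), Ddit3 2.80-fold (2.27 to 3.46), Calr 2.06-fold and Atf4 2.03-fold (1.95 to 2.12), while Ddit4 was 3.03-fold higher (2.66 to 3.45) and Sesn2 1.57-fold. Calr and Atf4 came under 2-fold with total count scaling, and Atf4 also with that of DESeq2. The median was -0.54 (-0.63 to -0.46), at percentile 0.07, and became -0.28 at percentile 4.20 after adjustment for length alone and -0.34 at percentile 0.65 after adjustment for length and GC content. The NF-kB and cytokine list went both ways, with 3 of 19 lower and 4 higher and a median of -0.36 at percentile 2.91, which became 0.00 at percentile 50 after adjustment for length and GC content, with 5 then lower and 3 higher. In it the chemokine genes Ccl4 (4.03-fold, 3.24 to 5.04), Ccl3 (2.90-fold, 2.71 to 3.11) and Cxcl2 (3.14-fold, 2.01 to 5.05) were lower and Ccl6 (3.43-fold, 3.04 to 3.89) and Bcl3 (2.44-fold, 2.04 to 2.92) higher.

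Ribosomal protein genes were lower in the library labelled P2x7-KO, where all 77 lay below equality. At least 2-fold lower were 43, and 34 were neither. The median log2 ratio was -1.07 (-1.09 to -1.03), below all 10000 random lists, and -0.68 after adjustment for length and GC content, again below all of them, with 18 then past 2-fold. Rpl41 (3.62-fold, 3.54 to 3.71), Rpl37a (3.67-fold, 3.52 to 3.82), Rpl38 (3.64-fold, 3.32 to 3.99) and Rps29 (3.95-fold, 3.18 to 4.94) led the list. These genes took 7.66% (7.65 to 7.68, Clopper-Pearson) of counts in the library labelled wild type and 4.13% (4.11 to 4.14) in the other. Many have processed pseudogenes, so their counts depend on how reads with several matches were treated.

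Respiratory chain genes followed the same direction. Of 30 nuclear genes of oxidative phosphorylation, 4 were at least 2-fold lower and 0 higher, among them Uqcrc1 (3.78-fold, 2.93 to 4.93), Cox7a2 (2.39-fold, 2.19 to 2.61), Cox6c (2.33-fold, 2.17 to 2.502) and Uqcrb (2.16-fold, 1.98 to 2.36). Their median of -0.60 (-0.63 to -0.53) lay below all random lists but became -0.15, at percentile 16.7, after adjustment for length alone, and -0.22, at percentile 1.94, after adjustment for length and GC content. Of 13 mitochondrially encoded genes 0 passed the rule. Their median was -0.64 (-0.66 to -0.59), at percentile 0.19, with ND4 1.95-fold lower (1.91 to 1.99) and CYTB 1.56-fold lower (1.54 to 1.58), and they took 3.09% (3.08 to 3.10) of counts in the library labelled wild type and 2.35% (2.34 to 2.36) in the other. No annotated length was found for these genes, so their median could not be adjusted for it. The percentile was matched on expression only, and mRNA genes of 107 to 1398 nt had a median of -0.57. The list median therefore cannot be told apart from the trend with transcript length.

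Of 30 DNA replication genes 0 passed the 2-fold rule in either direction, but their median of -0.41 (-0.44 to -0.36) lay at percentile 0.15 of random lists. Adjusted for length and GC content 1 was lower, Rfc2, at a log2 ratio of -1.11 (-1.20 to -1.01). Before it Rfc2 was at 1.85-fold lower (1.73 to 1.98), Rfc4 at 1.84-fold, Tyms at 1.60-fold and Pold1 at 1.58-fold, and Ccne2 at 1.67-fold higher. Among 30 mitosis genes, Cenpf alone passed the rule, at 2.504-fold higher (2.29 to 2.74). The median was 0.08, at percentile 63.6, and -0.03 after adjustment for length and GC content. The proliferation marker gene Mki67 was at 1.54-fold higher (1.497 to 1.58), a log2 ratio of 0.62 that became -0.03 after adjustment for length and GC content.

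Other members of the purinergic system went both ways. Of 17 genes counted besides P2rx7, 4 were at least 2-fold higher and 3 lower in the library labelled P2x7-KO, with a median log2 ratio of 0.39 (-0.13 to 0.50) at percentile 91.1 that turned to -0.38 among members with at least 100 counts and became 0.03 after adjustment for length and GC content, with 6 then higher and 3 lower. The nucleotide receptor genes P2ry6 (3.40-fold, 2.33 to 5.06) and P2ry1 (3.41-fold, 2.08 to 5.83), the ectonucleotidase gene Entpd1 (2.24-fold, 1.88 to 2.68) and the adenosine receptor gene Adora3 (2.10-fold, 1.46 to 3.06) were higher. P2ry14 (5.46-fold, 3.73 to 8.24), the nucleoside transporter gene Slc29a1 (2.31-fold, 2.13 to 2.495) and P2rx4 were lower. P2rx4, beside P2rx7 on chromosome 5 from 122707544 to 122729738, stood at 62.2 against 29.2 CPM (2.13-fold lower, 1.88 to 2.42).

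Of 14 inflammasome and interleukin-1 genes, the inflammasome sensor genes Nlrp3 (2.61-fold, 2.24 to 3.06) and Nlrp1b (6.37-fold, 2.68 to 18.4) were higher and 0 were lower, with Pycard at 1.20-fold lower and a list median of 0.17 at percentile 70.9. Nek7 was at 1.92-fold higher, a log2 ratio of 0.94 that was 1.01, past 2-fold, with total count scaling and 0.29 after adjustment for length and GC content. Of 25 calcium signalling genes, 4 were higher and 0 lower: Atp2b1 (2.88-fold, 2.61 to 3.18), Nfatc2 (2.93-fold, 2.30 to 3.77), Camk2d (3.73-fold, 1.89 to 8.03) and Prkcb (2.07-fold, 1.95 to 2.20). Their median was 0.43 (0.35 to 0.49), at percentile 99.45, and 0.36 after adjustment for length and GC content, at percentile 99.9. Of 16 adhesion and homing genes, Ccr1 (3.52-fold, 3.06 to 4.06) and Itga6 (2.14-fold, 1.94 to 2.37) were higher. Cxcr4 was at 1.87-fold higher, past 2-fold after adjustment for length alone (log2 ratio 1.199) but not for length and GC content (0.985). That median of 0.34, at percentile 98.7, became 0.14 at percentile 91.7 after adjustment for length and GC content. Of 10 branched-chain amino acid genes, Ppm1k was 2.34-fold higher (1.66 to 3.33), Bcat2 was at 1.72-fold lower, and the median was -0.33 at percentile 6.09. Of the 32 lists in all, 6 had a median above the random lists and 6 below.

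**Figure D3:**
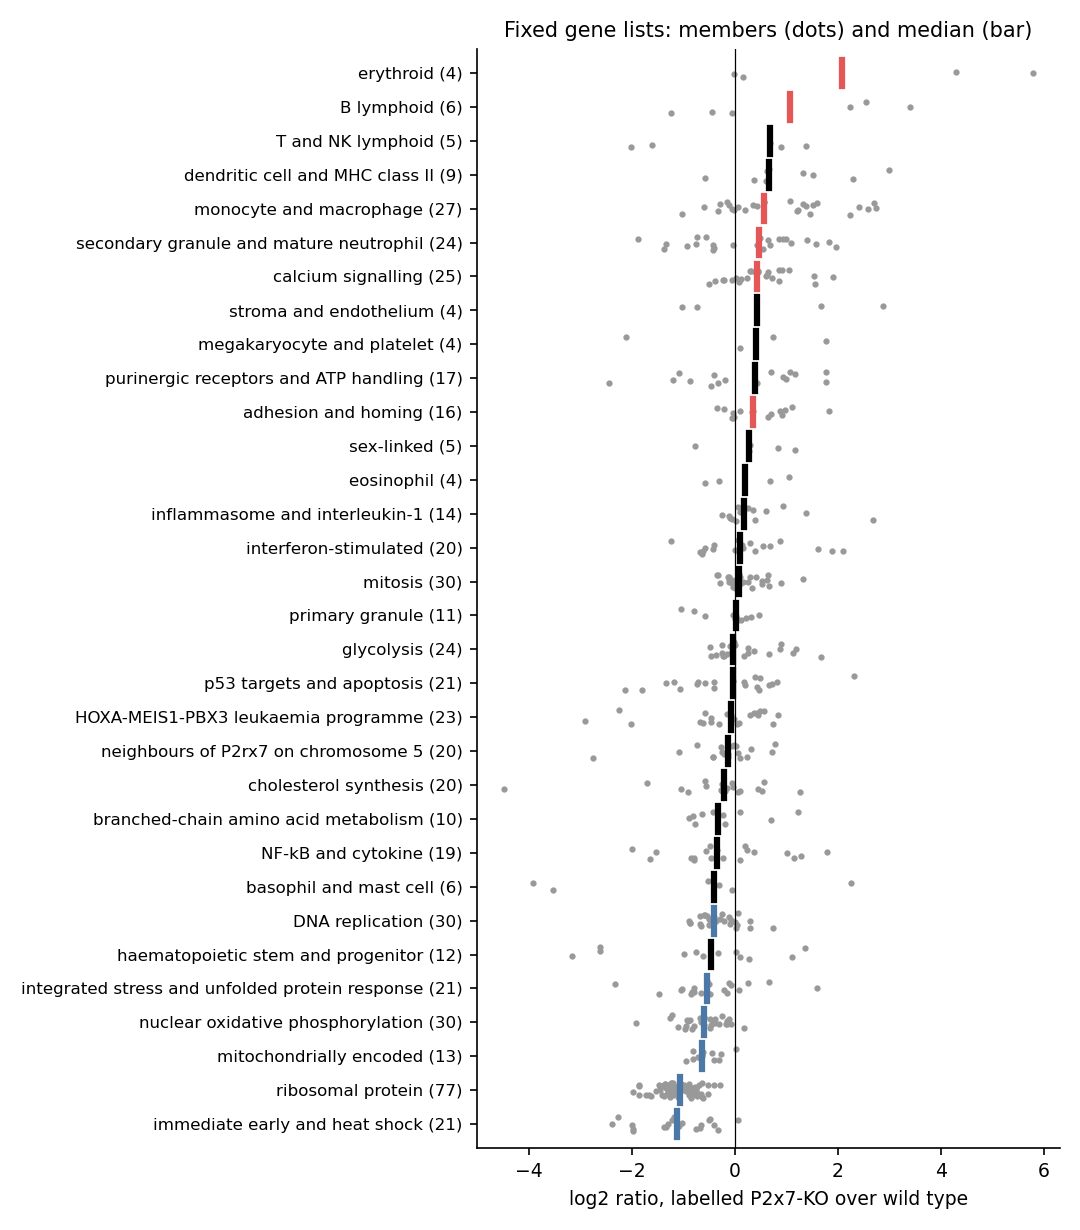
Log2 ratio of the library labelled P2x7-KO to the library labelled wild type (horizontal axis) for the members counted in both libraries (dots) of each gene list, with the number of members counted in brackets. The bar is the list median, coloured red or blue where it lay above or below the central 95% of random lists matched on expression; the lowest medians were -1.12 (immediate early and heat shock) and -1.07 (ribosomal protein).

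The ratio between the libraries followed transcript length. Over 10916 mRNA genes the rank correlation of the log2 ratio with the longest annotated transcript was 0.44, across genes, which are not independent replicates. Of 10 groups of genes ordered by length, that with the shortest transcripts, 107 to 1398 nt, had a median log2 ratio of -0.57, and that with the longest, 6729 to 123179 nt, a median of 0.63. The rank correlation with GC content was -0.35. Genes for snoRNA, a class of short non-coding RNA, took 0.0258% (0.0249 to 0.0267) of counts in the library labelled wild type and 0.0146% (0.0139 to 0.0153) in the other. In the same order, genes for ribosomal RNA took 0.207% and 0.108%, and those for small nuclear RNA 0.00331% and 0.000724%. Shares of long non-coding RNA (0.754% and 0.774%) and mRNA genes (95.38% and 96.69%) went the other way. Whether these shares follow length was not tested. After adjustment for length and GC content, 1034 genes were at least 2-fold higher and 718 lower among 12374 genes, of which 800 and 584 were among those called without it. Among the genes named here, Entpd1, Ppm1k, Cd93, Cenpf, Atp2b1, Itga6, Pdk1, Hsd17b7 and Ddx3y, all higher in the library labelled P2x7-KO, came under 2-fold with it, as P2rx7 did. So did Calr, S100a8, Stfa2, Ighm, Bst2, Gadd45a, Atf4, Cox7a2 and Uqcrb, all lower in that library. Of 185 named genes with counts in both libraries and an annotated length, 38 moved by over 1.5 times, of which 22 were past 2-fold before and after. Among those moved, log2 ratios came nearer to equality for Ccr2 (2.70 to 2.05), Nkg7 (-1.61 to -1.02), Ifih1 (1.87 to 1.1998), Ier3 (-1.98 to -1.39), Gadd45b (-2.13 to -1.49999), Trp53inp1 (2.31 to 1.66), Camk2d (1.90 to 1.23), Rpl41 (-1.86 to -1.22), Rpl37a (-1.88 to -1.197) and Rpl38 (-1.86 to -1.18). They lay further from it for P2ry14 (-2.45 to -3.28), Mllt3 (-2.62 to -3.27), Hba-a1 (4.29 to 4.92) and Ccl5 (1.37 to 1.97).

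**Figure D4:**
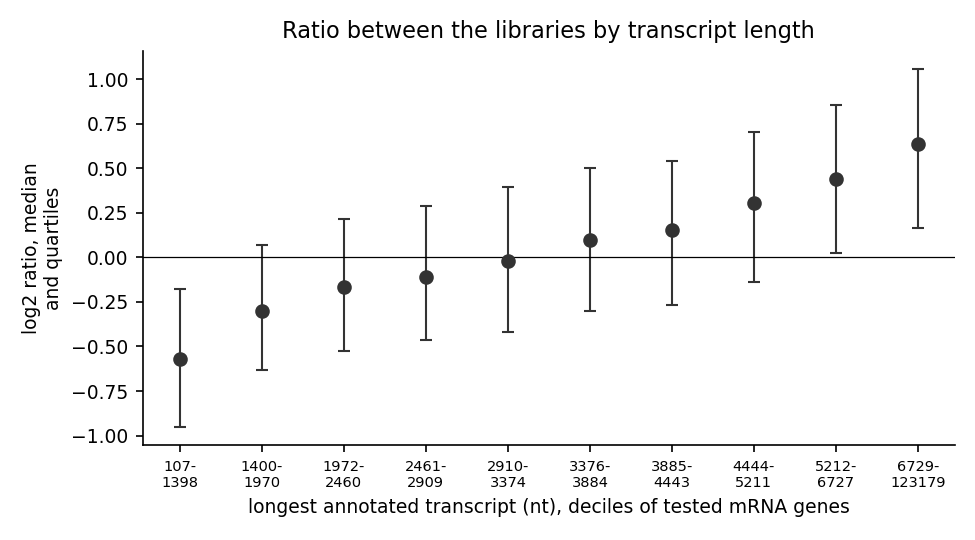
Median log2 ratio of the library labelled P2x7-KO to the library labelled wild type (points, with quartiles as bars) in 10 groups of 10916 mRNA genes ordered by their longest annotated transcript in nt. The median was -0.57 in the shortest group and 0.63 in the longest.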

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

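The adjustments for transcript length and GC content, and the restriction to genes with an annotated length, were chosen after seeing the data, and all other alternatives before. No paired analysis was possible because each group holds 1 library, and leaving out a library was not possible for the same reason. The P2rx7 log2 ratio of 1.18 stayed between 1.15 and 1.25 under the other scalings, thinning and the removal of abundant gene classes, and was 0.85 adjusted for length and 0.92 adjusted for length and GC content, under 2-fold in both. The counts of 1447 higher and 1196 lower genes became 2825 and 2521 at 1.5-fold, 298 and 252 at 4-fold, and 724 and 529 where the whole interval had to lie beyond 2-fold. The lower count was 704 with at least 100 counts per gene, 733 with the length adjustment and 718 with length and GC content. The adjustments ran on the 12374 genes with an annotated length, among which 1281 were higher and 1068 lower without adjustment, so fewer genes account for only part of the shift in the lower count, and the adjustments for the rest. The other shifts follow from stricter or looser rules or fewer genes. Under the other scalings the higher count lay between 1357 and 1637. The scalings moved all log2 ratios together by -0.03 to 0.07 against TMM, which exceeds the counting interval of abundant genes near equality and turns the sign of the glycolysis and p53 medians (to 0.03 and 0.02 with total counts) and of the primary granule median (upper quartile). Of the 12 lists outside the random lists, where run, B lymphoid lost this without the count filter, adhesion and homing without abundant gene classes, with 10 expression bins and with length and GC content, and oxidative phosphorylation and integrated stress with length alone. The mitochondrially encoded list has no adjusted value, and 3 lists each had none without abundant gene classes (erythroid, ribosomal protein and mitochondrially encoded) and with at least 100 counts (erythroid, T and NK lymphoid, and stromal and endothelial). Of 118 named genes past the 2-fold rule, 5 were no longer past it with total counts, Calr, Pecam1, Atf4 and Fdps among them, 3 with DESeq2's factors, Pecam1 and Atf4 among them, and 0 with upper quartile scaling or thinning. Of 117 with an annotated length, 24 were no longer past it with length and 21 with length and GC content, and of 112 outside the abundant classes 0 without those classes. In these runs 0 of the genes past the rule changed sign. Of 72 named genes not past it, 3 came past it with total counts, 2 with DESeq2's factors, 1 with upper quartile scaling and 0 with thinning, and of 68 in each other run 1 without abundant gene classes, 7 with length and 6 with length and GC content. Some changes are missed at this depth: 94% of simulated 2.5-fold higher and 87.5% of 2.5-fold lower genes were called. Whether the missed genes were those with few counts was not examined.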

Other observations

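The tests of explanations reported here were chosen after the results were seen, except the count of lists within which the ratio follows transcript length. Several further lists held single genes that stood apart while their medians lay within the random lists. Of 20 cholesterol synthesis genes, 3 were at least 2-fold lower in the library labelled P2x7-KO and 1 was higher, with Fdps 2.06-fold lower (1.92 to 2.21) but under 2-fold with total count scaling (log2 ratio -0.98), Hsd17b7 2.40-fold higher (1.72 to 3.39) and a median log2 ratio of -0.21 at percentile 8.21. Of 24 glycolysis genes, 3 were higher and 0 lower, among them the glucose transporter gene Slc2a3 (3.17-fold, 2.52 to 4.01) and Pdk1 (2.28-fold, 2.09 to 2.497), with a mean of 0.19 and a median of -0.04, at percentile 40.5, that turned to 0.03 under total count scaling and to 0.13, at percentile 90.1, after adjustment for length and GC content, with 5 then higher. Of 21 p53 target and apoptosis genes, 4 were lower, Gadd45b (4.39-fold, 3.98 to 4.85), Cdkn1a (2.54-fold, 2.24 to 2.88), Phlda3 (3.51-fold, 2.01 to 6.44) and Gadd45a (2.26-fold, 1.95 to 2.63), and Trp53inp1 was 4.97-fold higher (3.90 to 6.39), with a median of -0.05, at percentile 34.9, that turned to 0.02 under total count scaling, to 0.01 after that adjustment and to 0.17, at percentile 76.2, among members with at least 100 counts.

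Of 20 interferon-stimulated genes, 3 were higher, Ifih1 (3.67-fold, 2.72 to 5.01), Mx1 (3.05-fold, 2.29 to 4.11) and Rsad2 (4.30-fold, 1.42 to 17.5), and Bst2 was 2.37-fold lower (2.07 to 2.72), with a median of 0.10 at percentile 52.5. Of 4 eosinophil genes, Ear2 was 2.06-fold higher (1.34 to 3.21), with a median of 0.19 at percentile 59.1. That median turned to -0.18 without the count filter and was 0.71, at percentile 95.4, after adjustment for length and GC content, with 2 then higher. Of 4 stromal and endothelial genes, Eng (7.32-fold, 4.47 to 12.7) and Cxcl12 (3.18-fold, 1.23 to 9.69) were higher, the latter with an interval that included equality after adjustment for length and GC content (log2 ratio 1.36, -0.01 to 2.96), and Pecam1 was 2.05-fold lower (1.94 to 2.18) but just under 2-fold with total count and DESeq2 scaling (log2 ratios -0.97 and -0.9997), with a median of 0.43 at percentile 82.1. After that adjustment 1 of the 4 was higher and 1 lower. Of 20 neighbours of P2rx7 on chromosome 5, P2rx4 and Tmem120b (39 against 6 counts, 6.80-fold, 2.86 to 19.7) were lower and 0 were higher, with a median of -0.13 at percentile 21.1.

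P2rx7 was 2.27-fold higher in the library labelled P2x7-KO. The median of genes of like length and GC content does not account for all of it. The log2 ratio was 1.18 (0.95 to 1.41) before adjustment and 0.92 (0.695 to 1.15) after, above equality but under 2-fold because such genes were higher too. These intervals leave out the spread among such genes, so they do not show that P2rx7 stands apart from them. Unadjusted, mRNA genes of 4444 to 5211 nt, the length group of P2rx7 (4936 nt), had quartiles of -0.14 to 0.70, below its ratio. A more monocytic state or more monocytic cells in that library was considered as an explanation. The adjusted P2rx7 ratio lay at percentile 51.9 of the monocyte and macrophage list, within its quartiles of 0.31 to 1.72. Quartiles this wide would also hold a gene raised for another reason, so the position does not decide for or against that explanation. The c-Kit gate should remove mature monocytes, and this explanation does not say why a knockout kept transcript. An exchanged or wrong label could not be excluded: the library labelled wild type held 44.1% (37.7 to 51.6) of the P2rx7 level of the other. That is not near absence, but a partial knockdown under exchanged labels would also leave a share between absence and equality. An allele or knockdown that leaves counted transcript would account for P2rx7 being present in the library labelled P2x7-KO. By itself it would not account for the higher level there. Counts per gene and 1 library each do not settle which of these holds.

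Longer transcripts were higher and shorter ones lower in the library labelled P2x7-KO. A few groups of short transcripts moving together do not explain this, because without ribosomal protein, mitochondrial, respiratory chain and histone genes the rank correlation over 10610 genes was still 0.419. Within gene lists the rank correlation was positive in 16 of 18 lists with 15 or more members. RNA quality or library preparation acting by length would give this. So would any other origin of the correlation of 0.44 over all mRNA genes, so the count does not decide between them. A genotype effect on transcripts by length stays open and untested, since each genotype has 1 library.

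Immediate early genes were lower in the library labelled P2x7-KO, and the length and GC trend does not account for this, with an adjusted list median of -0.85 below all 10000 random lists, although 8 members and not 13 were then at least 2-fold lower. After adjustment 16 of 17 immediate early members were lower, and the 4 heat shock members had a median of -0.91. These are members of the list that shows the pattern, so their values do not bear on its origin. Longer handling or stress of the cells in the library labelled wild type and an effect of genotype cannot be told apart, because each library has its own genotype and its own handling.

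Both libraries held Xist, at 53.9 CPM in the library labelled wild type and 31.6 CPM in the other, together with the Y-linked genes Ddx3y (37.4 and 84.1 CPM), Eif2s3y (90.1 and 109.3 CPM), Uty (11.8 and 21.2 CPM) and Kdm5d (27.9 and 33.8 CPM). Xist was 1.71-fold lower (1.51 to 1.94) in the library labelled P2x7-KO, while the Y-linked genes were all higher there before adjustment. The list median of 0.28, at percentile 76.0, thus joins opposite directions. The lowest Xist or Y-linked value, 11.8 CPM for Uty in the library labelled wild type, lay above the detection limit of 0.247 CPM there. Xist and Y-linked transcript at these levels argue against only male or only female cells in either library. Whether the shares of the sexes differed between the libraries was not tested, nor whether cells of both sexes had the labelled genotype. Adjusted for length and GC content, Xist was at a log2 ratio of -1.61, past 2-fold, Kdm5d turned from 0.28 to -0.42, and the list median was 0.06. Among abundant genes, chosen after their values were seen, the uncharacterised LOC108169013 had 5052 counts in the library labelled wild type and 48887 in the other (9.24-fold higher, 8.98 to 9.52). The galectin gene Lgals1 was 3.52-fold lower (3.43 to 3.62) at 1740 against 494.0 CPM, and the prostaglandin-degrading enzyme gene Hpgd 2.46-fold higher (2.40 to 2.53). COX1 had 165280 and 142304 counts while COX2, from the same mitochondrial genome, had 1186 and 756.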
